A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

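Total RNA of SK1 yeast was labelled as biotinylated cDNA and hybridized to Affymetrix arrays, per the labels from 600 ng RNA. Wild-type (WT) and ime4-/- (ime4) cells were sampled in rich medium (YPD) and after 4 h in sporulation medium (SPO, 1% potassium acetate). The groups held 2 arrays (WT in YPD), 3 (WT in SPO), 2 (ime4 in YPD) and 2 (ime4 in SPO). The labels call them biological replicates, so the p-values reflect the spread between such replicates. Mating type, ploidy, the extent of the deletion and array dates were not given in the sources used here.

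The deposited values are in the unit intensity, on a linear scale, and per the submitters' processing notes they come from RMA. The software and settings of RMA were not given in the sources used here. RMA fits all arrays to a common distribution of values, so a shift of all transcripts together would not be visible, and differences are relative to the other transcripts on the array. The log2 of each value was taken with no offset. The table had 9676 probe sets. Gene names came from an annotation of the array joined by gene identifier to the yeast gene table of assembly R64. Of the 6772 named probe sets, 5359 belonged to 5311 Saccharomyces cerevisiae genes and were tested, and 1413 belonged to another species. The other 2904 had no gene name (39 of them reporters) and were left out of the tests. The join updated 12 symbols, and 1 probe set listed several symbols. The names of 126 tested sets carry an ending that marks probes shared with other sequences. Among the genes named in the text, HMLALPHA1 (which shares sequence with the MAT alpha1 gene), YAR066W and HTA2 carry such an ending.

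The background level of each array was the 95th percentile of the 1413 probe sets of the other species. It lay at intensities of 8.1 to 9.64 (log2 3.02 to 3.27), and 96.21% to 98.19% of the tested sets lay above it. A gene at or below this level on every array of a group is called at background there. Its fold is then computed against the level itself and written as "at least". Where only some arrays of a group lay above background, the size of the fold is uncertain. The medians of the tested sets, on the log2 scale, were 7.75 and 7.73 (WT in YPD), 7.85, 7.86 and 7.83 (WT in SPO), 7.76 and 7.77 (ime4 in YPD), and 7.80 and 7.81 (ime4 in SPO). Replicate arrays correlated across genes with r from 0.998 to 0.999, and their median absolute log2 difference was 0.0532 to 0.0679.

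The choices that follow were made before the data were examined. Group means were fitted to all 9 arrays in 1 model with limma 3.58.1 in R 4.3.3 (lmFit, eBayes). The contrasts were ime4 against WT in SPO and in YPD, SPO against YPD in WT and in ime4, and the difference between the last 2 (the genotype by medium interaction). Tests were two-sided, with Benjamini-Hochberg adjustment over the 5359 tested sets and a threshold of 0.05. Below, a gene rose or fell when it passed this threshold. Counts of genes are counts of tested probe sets. The median residual SD was 0.0646 log2, with 5 residual and 4.07 prior degrees of freedom. The median SE was 0.0586 for the genotypes in SPO, 0.0642 for the genotypes in YPD and 0.087 for the interaction. The procedure was tested on simulated data of this size, with 50 genes shifted per size, in ime4 in SPO only, and independent noise. It called 54% of genes shifted by 0.25 log2 and 100% of genes shifted by 0.5 in the SPO genotype contrast, and 2% and 84% in the interaction. It called 10, 8 and 7 unchanged genes in the 3 simulated contrasts. In the data a far larger share of the tested sets passed, 40% to 90% by contrast, which makes the adjustment less strict. The simulated shares and false calls therefore do not carry over to the data.

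The named genes were the 8 largest rises and the 8 largest falls per contrast among genes past the threshold whose arrays did not overlap between the groups. For the interaction they were the 5 largest in each direction with no condition on overlap. IME4 and every measured member of the lists of the m6A methyltransferase complex, the meiotic entry regulators and the IME4 neighbours were named in addition, and up to 4 members of each other list with the smallest p. Of several probe sets of a gene, the 1 with the highest mean was used. Of 29 fixed gene lists, 28 had at least 3 measured genes and were tested with limma camera at a preset correlation of 0.01, adjusted over all lists and the 5 contrasts together. Alternatives were camera with a correlation estimated from the residuals and fry. Members past the threshold were counted with the adjustment over all genes and adjusted over the list alone. The responses of both genotypes were compared across genes by Pearson and Spearman correlation and a total least squares slope, with no p-value, since genes are not independent replicates.

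The other alternatives were quantile normalization, centring of each array on its median, leaving out the 25% of probe sets with the lowest means, an intensity trend with robust variances, array weights, the replicate number as a block, only the arrays of the groups compared, a 2-fold threshold, and leaving out each array in turn. Sets of a-specific, alpha-specific and haploid-specific genes were written after the values of these genes had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.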

Results

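IME4, the RNA N6-adenosine methyltransferase that yeast needs for efficient sporulation, was above background on every WT array and on no ime4 array. In WT its mean log2 intensity was 5.35 (SD 0.0025, n = 2) in YPD and 7.12 (SD 0.0203, n = 3) in SPO, a rise of 1.77 (SE 0.099, adjusted p = 5.74e-08). The ime4 arrays read 2.36 in YPD and 2.34 in SPO, under the background level of about 3. The signal of its probes was at least 4.47-fold lower in ime4 than in WT in YPD (adjusted p = 1.09e-07) and at least 17.1-fold lower in SPO (adjusted p = 2.9e-09). Whether the probes lie in the deleted part of the gene was not known. Of the 2 measured neighbours of IME4 on chromosome VII, HOS2 did not pass the threshold between the genotypes, except in YPD without WT replicate 1 (adjusted p = 0.0422). COX13, which encodes a subunit of cytochrome c oxidase, fell by 0.30 log2 in SPO (adjusted p = 0.000221) and by 0.14 in YPD (adjusted p = 0.046, lost with quantile normalization at 0.0804, with the replicate number as a block at 0.073, and without any of the 4 arrays at 0.0514 to 0.212).

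The largest differences between the genotypes were in transcripts that mark the mating type. The a1 transcript, read by the HMRA1 probe set, stood at 8.04 log2 in WT in YPD and was at background in ime4, at least 28.7-fold lower. In SPO it was 55.4-fold lower in ime4, a size that is uncertain because 1 of 2 ime4 arrays lay above background. The alpha1 transcript, read by the HMLALPHA1 probe set, was 26.1-fold higher in ime4 in YPD and 13.4-fold higher in SPO. All 7 a-specific genes examined were lower in ime4 in both media, with medians of -2.98 log2 in YPD and -2.08 in SPO, and all 5 alpha-specific genes were higher, with medians of 5.43 and 3.46. The a-factor gene MFA2 was at least 165-fold lower in YPD (adjusted p = 5.13e-13) and 30.7-fold lower in SPO. The alpha-factor receptor gene STE2 was 117-fold lower in YPD (1 of 2 ime4 arrays above background) and lower by 3.46 log2 in SPO. The a-factor receptor gene STE3 was 58.2-fold higher in YPD and 3.46 log2 higher in SPO, and the alpha-factor gene MF(ALPHA)1 48.3-fold and 20.2-fold higher. Haploid-specific genes, which cells with both mating types repress, were higher in ime4 for 10 of 11 genes in YPD (median 1.31) and 11 of 11 in SPO (median 1.08). The a-specific, alpha-specific and haploid-specific sets were written after these values had been seen. Every ime4 array differed from every WT array in the order of a1 and alpha1. Each comparison of the genotypes, that of IME4 included, is therefore also a comparison of these mating-type patterns.

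**Figure D1:**
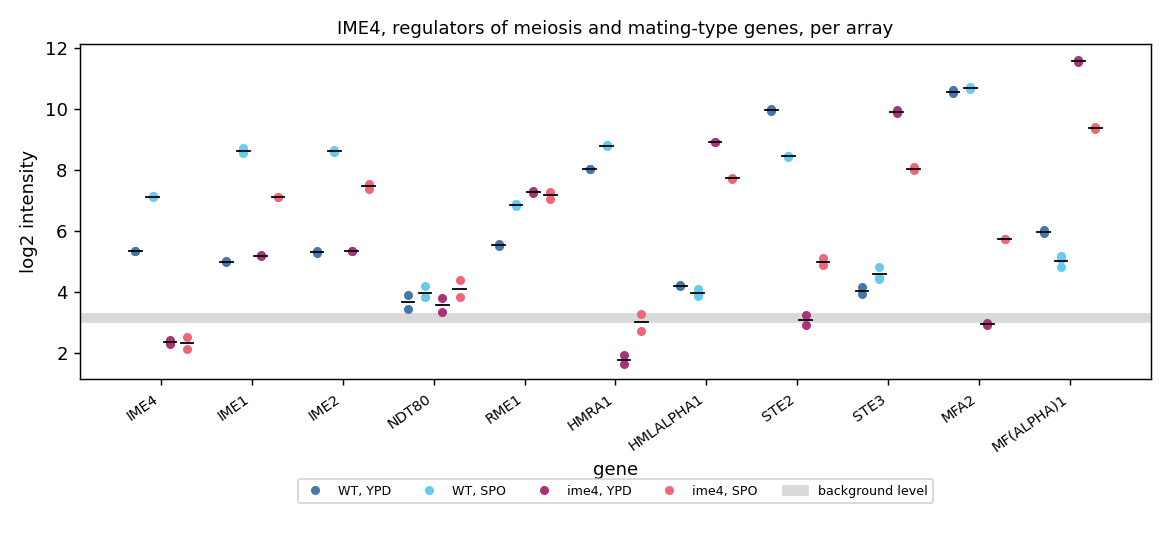
Points show the log2 intensity of each array by gene and group, short bars the group means, and the grey band the background levels of the 9 arrays (3.02 to 3.27). IME4 and HMRA1 are high in WT and low or at background in ime4, HMLALPHA1 is the reverse, and IME1 and IME2 rise in SPO in both genotypes but to lower levels in ime4.

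On transfer of WT cells from YPD to SPO, genes of ribosomes and translation fell, and genes of acetate use, beta-oxidation and stress rose, as did several regulators of meiotic entry. Of 5359 tested probe sets, 2511 rose and 2310 fell, and 1183 rose and 1133 fell at least 2-fold. The largest rises included RGI2, a gene of respiratory energy metabolism, at least 902-fold, the acetate transporter gene ADY2 (459-fold, with 1 of 2 YPD arrays above background), the carnitine carrier gene CRC1 (401-fold), YLR012C (360-fold), the acyl-CoA oxidase gene POX1 (at least 169-fold), the catalase gene CTA1 (301-fold), SPG4 (281-fold) and the formate dehydrogenase gene FDH1 (269-fold). The largest falls were in the nucleolar genes NOP1 (30.8-fold), NIP7 (19.4-fold), NSR1 (17.6-fold) and NOP13 (17.0-fold), in URA7 of CTP synthesis (18.5-fold), ELO2 of fatty acid elongation (17.3-fold) and INA1 (16.5-fold), and in the ribosomal protein gene RPL6B (16.4-fold).

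All 122 measured cytosolic ribosomal protein genes fell in WT (median -2.07 log2, camera adjusted p = 1.74e-22), as did all 68 ribosome biogenesis genes (median -2.70, adjusted p = 2.37e-16) and all 32 translation factors (median -1.54, adjusted p = 7.78e-09). These 3 calls held with an estimated correlation, as did those of fatty acid beta-oxidation (26 of 27 rose, median 3.05), the general stress response (30 of 31, median 1.93) and autophagy (39 of 40, median 1.44). HSP26 rose by 5.55 log2 and the autophagy gene ATG8 by 2.99. All 21 genes of gluconeogenesis, the glyoxylate cycle and acetate use rose, with a median of 6.55 (adjusted p = 7.79e-09, or adjusted p = 0.0644 with an estimated correlation). PCK1, which encodes the entry enzyme of gluconeogenesis, rose by 6.37. All 17 genes of the tricarboxylic acid cycle rose (median 1.57, adjusted p = 1.87e-05, 0.112 with an estimated correlation), among them CIT3 by 5.98. Of the 38 respiratory chain genes 37 rose (adjusted p = 2.48e-06, 0.0588 with an estimated correlation), and of the 31 genes under nitrogen catabolite repression 27 rose (adjusted p = 1.26e-05, 0.0754 with an estimated correlation), GAP1 by 6.54. DNA replication genes fell in 34 of 43 cases (median -0.78, adjusted p = 0.000335, 0.105 with an estimated correlation). RNR1 fell by 3.42 and POL30 by 2.70. Genes of mitotic G1 and budding fell as well (23 of 30, with 5 higher, adjusted p = 0.00429, 0.0754 with an estimated correlation, lost without the dimmest 25% of probe sets at 0.128), as did ergosterol genes (18 of 25, with 5 higher, adjusted p = 0.0165, 0.291 with an estimated correlation). The iron regulon (21 of 29, adjusted p = 0.00112), phosphate starvation (14 of 17, adjusted p = 0.00429) and sulfur assimilation (19 of 27, adjusted p = 0.015) rose, with adjusted p = 0.108, 0.0814 and 0.18 with an estimated correlation. The lists of glucose use did not pass: glycolysis had 7 higher and 14 lower of 21 genes (adjusted p = 0.285), and hexose transport 9 higher and 2 lower of 14 (adjusted p = 0.239). Adjusted over the list alone, each of these counts was the same.

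Several regulators of meiotic entry rose in WT. The master regulator IME1 rose 12.4-fold (log2 3.64, SE 0.0524, adjusted p = 6.09e-12) and its target kinase gene IME2 9.88-fold. SLZ1, a partner of Ime4, rose 10.8-fold, PHO92, which encodes a reader of m6A, at least 9.33-fold, and RIM4, a translational repressor in meiosis, 5.42-fold. NDT80, the activator of the middle genes, did not pass the threshold (log2 0.28, SE 0.208, adjusted p = 0.226), and its level was near background on every array. RME1, a repressor of IME1, rose 2.49-fold. Of 12 entry regulators 9 rose and 2 fell (adjusted p = 0.0318, 0.189 with an estimated correlation). The list holds repressors such as RME1 beside activators such as IME1, so its direction is not a direction of meiotic entry. Of 33 early recombination genes 23 rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 0.57, or 0.42 with values under background set to it (adjusted p = 0.034, 0.209 with an estimated correlation). CSM4 rose by 2.86. Of 46 middle genes 28 rose and 10 fell (28 and 9 adjusted over the list alone; median 0.48, or 0.28 at background, adjusted p = 0.102). CDC5 fell by 1.48. Of 14 genes of the spore wall 11 rose (adjusted p = 0.0356, 0.24 with an estimated correlation), SPS100 by 2.85. The spore wall call was also lost without WT replicate 2 in YPD, a fit that leaves 1 array in that group. With the dimmest 25% of probe sets left out, the calls of the entry, early and spore wall lists were lost in WT (adjusted p = 0.131, 0.863 and 0.234).

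In ime4 cells the lists of ribosomes, translation and acetate use moved in the same directions as in WT, with medians smaller in size. For the early, middle and spore wall lists no shared shift from the WT response passed with camera (interaction adjusted p = 0.941, 0.725 and 0.945). Single members did respond differently, in both directions, among them CSM4 (-1.154 log2), CDC5 (0.7663) and SPS100 (-0.3553). In ime4, 2357 probe sets rose and 2252 fell from YPD to SPO, 922 and 868 of them at least 2-fold. RGI2 rose at least 650-fold, YLR012C 243-fold, CTA1 171-fold, POX1 at least 136-fold, CRC1 160-fold, the thiolase gene POT1 159-fold, ADY2 136.5-fold and SPG4 114-fold. The largest falls were in the glucose transporter gene HXT4 (12.0-fold), RPS0B (10.1-fold), MF(ALPHA)2 (9.98-fold), AAH1 (9.28-fold), NIP7 (9.26-fold), NOP1 (9.06-fold), RPL6B (8.67-fold) and URA7 (8.55-fold). Of 122 ribosomal protein genes 121 fell (median -1.21, adjusted p = 4.58e-20), as did 54 of 68 ribosome biogenesis genes, of which 9 rose (median -1.41, adjusted p = 3.23e-08). All 21 genes of gluconeogenesis and acetate use rose (median 4.97, adjusted p = 1.2e-09, 0.0588 with an estimated correlation). Stress genes (28 of 31, adjusted p = 5.5e-08), autophagy (36 of 40, adjusted p = 5.63e-07) and beta-oxidation (27 of 27, adjusted p = 4.47e-09) rose too, and these calls held with an estimated correlation. Proteasome genes fell (24 of 30, with 3 higher, adjusted p = 0.00295, 0.218 with an estimated correlation). IME1 rose 3.79-fold, IME2 4.37-fold, SLZ1 6.18-fold, PHO92 at least 5.09-fold and RIM4 2.18-fold. NDT80 did not pass the threshold (log2 0.52, adjusted p = 0.0573), but did with an intensity trend (0.0301), without ime4 replicate 2 in YPD (0.0273) and without ime4 replicate 1 in SPO (0.016). Of the early genes 22 of 33 rose (adjusted p = 0.0274, 0.195 with an estimated correlation), a call whose direction was lost with the dimmest 25% of probe sets left out (adjusted p = 0.94). Of the middle genes 25 of 46 rose and 10 fell (adjusted p = 0.0391, 0.255 with an estimated correlation, 0.964 without the dimmest 25%). Of the spore wall genes 13 of 14 rose (adjusted p = 0.00661, 0.158 with an estimated correlation, 0.132 without the dimmest 25%). Of the entry regulators 9 of 12 rose and 1 fell (adjusted p = 0.0156, 0.155 with an estimated correlation, 0.0706 without the dimmest 25%). The counts adjusted over the list alone were the same for these lists.

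Across the 5359 probe sets the responses of ime4 and WT correlated with r = 0.927 (rho = 0.906), and the slope of ime4 on WT was 0.792, with an SD of 0.0032 over the 24 ways to pick 1 array per group. Of the 2316 sets changed at least 2-fold in WT, 98.3% had the same sign in ime4. The interaction test called 3433 probe sets, 1579 with a higher and 1854 with a lower difference in ime4. Of the 1183 sets that rose at least 2-fold in WT, the response was lower in ime4 for 818 and higher for 78, and of the 1133 that fell, the response was less negative in ime4 for 849 and more negative for 53. In ime4, 3 of the 1183 fell and 19 of the 1133 rose. Measured as a log2 difference, the smaller fall was most marked for ribosome biogenesis (66 of 68 genes with a positive interaction, 67 adjusted over the list alone, median 1.25, adjusted p = 5.67e-23) and ribosomal proteins (112 of 122, 113 adjusted over the list alone, median 0.83, adjusted p = 9.78e-24). Genes of gluconeogenesis and acetate use rose less in ime4 (19 of 21 negative, median -1.32, adjusted p = 1.66e-07, 0.0754 with an estimated correlation). The ratio of the mean response in ime4 to that in WT was 0.511 for ribosome biogenesis, 0.627 for ribosomal proteins, 0.593 for phosphate starvation, 0.634 for the iron regulon, 0.719 for the tricarboxylic acid cycle, 0.735 for autophagy, 0.789 for gluconeogenesis and acetate use, 0.881 for beta-oxidation and 1.28 for sulfur assimilation. It was 0.7 for translation factors and 0.81 for stress. With 95% intervals from resampled genes, it was 0.744 for the entry regulators (0.48 to 1.31) and 0.897 for nitrogen catabolite repression (0.778 to 1.02). For the spore wall list it was 1.11 (0.794 to 1.74). Ratios were computed only for lists with a mean WT response of at least 2-fold, and not for the m6A list, which holds IME4. DNA replication and mitotic G1 and budding were therefore not compared in this way. The largest single interactions were positive for STE2 (3.42 log2), CDA2 (2.77), MFA2 (2.67), SPB1 (2.63) and RFU1 (2.41), and negative for ADH2 (-3.28), PHO84 (-2.49), URA1 (-2.46), ARO9 (-2.41) and STE3 (-2.40). MFA2 and CDA2 were at background in ime4 in YPD, where STE2 was above it on 1 of 2 arrays and CDA2 in WT on 1 of 2, so the sizes and order of these 3 are uncertain.

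**Figure D2:**
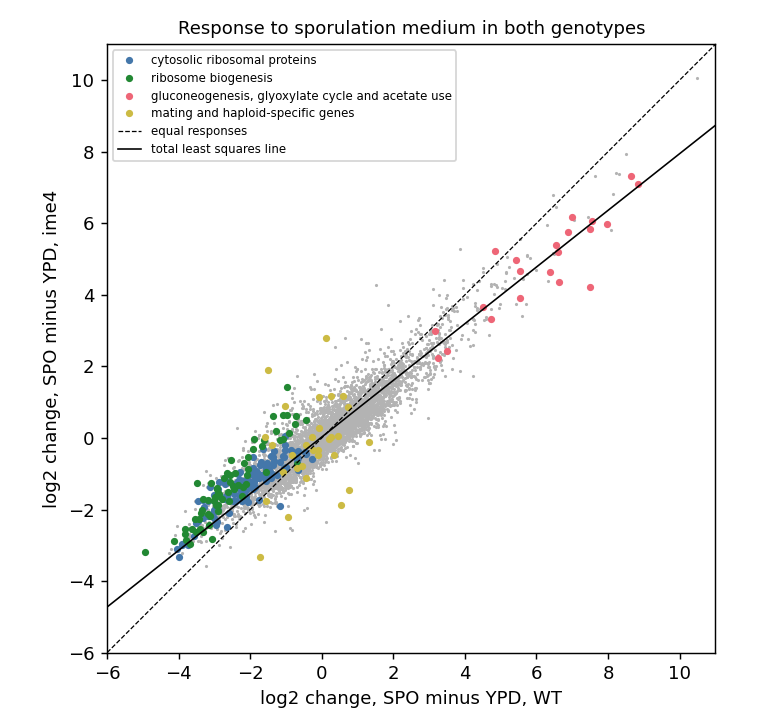
Each point is a probe set, with its log2 change from YPD to SPO in WT (horizontal) and in ime4 (vertical); colours mark 4 gene lists, the dashed line equal responses and the solid line the total least squares fit. The slope is 0.792, and most ribosome biogenesis genes lie above the line of equal responses, with a smaller fall in ime4 than in WT.

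In SPO, ime4 cells held lower levels of IME1 and of several regulators of meiosis than WT cells, and higher levels of the machinery that makes ribosomes. In all, 1827 probe sets were higher and 2109 lower in ime4 (1967 and 1912 with centring), but 306 higher and 92 lower at least 2-fold. IME1 was 2.88-fold lower (7.10, SD 0.00668, n = 2 against 8.63, SD 0.0797, n = 3, adjusted p = 2.57e-08), IME2 2.22-fold, RIM4 2.19-fold, PHO92 1.90-fold, RIM11 1.54-fold and SLZ1 1.41-fold. UME6 and SUM1, which encode repressors of meiotic genes in vegetative cells, were 2.08-fold and 2.88-fold higher. NDT80 did not differ past the threshold (log2 0.15, SE 0.208, adjusted p = 0.535), nor did MUM2, KAR4, MCK1 and RIM15. KAR4 was lower past the threshold with quantile normalization (adjusted p = 0.0488), with the replicate number as a block (0.0128) and without WT replicate 3 in SPO (0.00738), and MCK1 without ime4 replicate 2 in SPO (0.0404). RME1 was 1.23-fold higher, RIM101 lower (log2 -0.38) and RSF1 1.36-fold lower. The early list went both ways (8 of 33 higher, 11 lower, adjusted p = 0.924), as did the middle list (12 and 13 of 46, 12 and 12 adjusted over the list alone, adjusted p = 0.945) and the spore wall list (4 and 4 of 14, adjusted p = 0.945). For the early list the median was slightly positive and the test direction negative. The entry regulators (3 higher, 6 lower of 12, adjusted p = 0.307) and the m6A list (0 higher, 3 lower of 5, adjusted p = 0.0515) did not pass as lists. The higher entry regulators were the repressor genes RME1, UME6 and SUM1, while IME1, IME2 and RIM4 were among the lower ones. Camera tests for a shared direction, so opposite changes within this list can cancel. The m6A list, which holds the deleted gene IME4, passed with the replicate number as a block (adjusted p = 0.0439) and without any of 6 arrays (0.0332 to 0.0499).

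Outside the mating-type genes, the largest rises in ime4 in SPO were in SVS1 (5.91-fold), the ribosome biogenesis genes SPB1 (5.72-fold) and PRP43 (5.59-fold), and RFU1 (5.33-fold). AFB1, an a-factor barrier gene of alpha cells, was 17.3-fold higher. The largest falls, beside HMRA1, MFA2, STE2 and IME4, were in the a-agglutinin gene AGA2 (19.3-fold, with 1 of 2 ime4 arrays above background), URA1 of pyrimidine synthesis (17.2-fold, adjusted p = 4.15e-11), the daughter-cell wall gene DSE2 (6.15-fold) and YNL146C-A (6.11-fold).

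Of the ribosomal protein genes, 118 of 122 were higher in ime4 in SPO (119 adjusted over the list alone, median 0.82, camera adjusted p = 3.67e-25), and 66 of 68 ribosome biogenesis genes were higher with 1 lower (median 1.10, adjusted p = 2.06e-20). RPL8B was 3.16-fold and MAK5 4.46-fold (log2 2.16) higher. Translation factors followed (23 higher, 2 lower of 32, adjusted p = 1.87e-05), with TIF3 3.41-fold higher. These 3 calls held with an estimated correlation (adjusted p = 0.0291, 0.0272 and 0.0291). Sulfur assimilation (22 higher, 1 lower of 27, adjusted p = 4.83e-06), amino acid biosynthesis (30 and 10 of 44, adjusted p = 0.00145) and DNA replication (25 and 7 of 43, adjusted p = 0.00429) were also higher. With an estimated correlation these gave adjusted p = 0.0624, 0.112 and 0.14. On the same arrays MFA2 was 30.7-fold lower. CYS3 was 2.48-fold, HOM3 2.36-fold and POL30 2.81-fold higher in ime4.

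The genes of acetate use and respiration were lower in ime4 in SPO, on the same arrays on which the alpha1 transcript was 13.4-fold higher. This held for all 21 genes of gluconeogenesis and acetate use (median -0.65, adjusted p = 1.12e-05, 0.108 with an estimated correlation), among them ACS1 (2.23-fold) and the activator gene CAT8 (2.13-fold). It held for all 17 genes of the tricarboxylic acid cycle (median -0.45, adjusted p = 1.64e-05, 0.112 with an estimated correlation) and 34 of 38 respiratory chain genes (median -0.33, adjusted p = 1.6e-06, 0.0588 with an estimated correlation). Stress genes fell in 22 of 31 cases with 5 higher (adjusted p = 0.000363, and 0.0498 with an estimated correlation), SIP18 2.88-fold. Autophagy genes were lower in 31 of 40 cases with 4 higher (5 higher adjusted over the list alone, adjusted p = 0.000222, 0.0624 with an estimated correlation), PRB1 2.57-fold. The lists of nitrogen catabolite repression (20 lower, 5 higher of 31, adjusted p = 0.0137), the proteasome (21 and 2 of 30, adjusted p = 0.00345), the iron regulon (19 and 4 of 29, adjusted p = 0.00429) and beta-oxidation (17 and 2 of 27, adjusted p = 0.0243, lost without the dimmest 25% at 0.0598) were lower as well. With an estimated correlation they gave adjusted p = 0.189, 0.222, 0.133 and 0.137. The other lists did not pass in SPO. They were glycolysis (6 higher, 8 lower of 21, adjusted p = 0.834, with a positive median and a negative mean), hexose transport (5 and 7 of 14, adjusted p = 0.931), histones (1 and 5 of 8, adjusted p = 0.609), mitotic G1 and budding (18 and 9 of 30, adjusted p = 0.191), the mating and haploid-specific genes (17 and 9 of 30, adjusted p = 0.0653, but 0.0214 without the dimmest 25% and 0.0437 without ime4 replicate 2 in SPO), phosphate starvation (3 and 9 of 17, adjusted p = 0.13), ergosterol (12 and 7 of 25, adjusted p = 0.104) and strain marker loci (7 and 2 of 10, adjusted p = 0.0999). For hexose transport the median and the test were negative and the mean positive. The mating list holds a-specific genes, lower in ime4, beside alpha-specific genes, higher in ime4, which can cancel in a test of a shared direction. Where no other count is given, the counts adjusted over the list alone were the same in SPO.

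**Figure D3:**
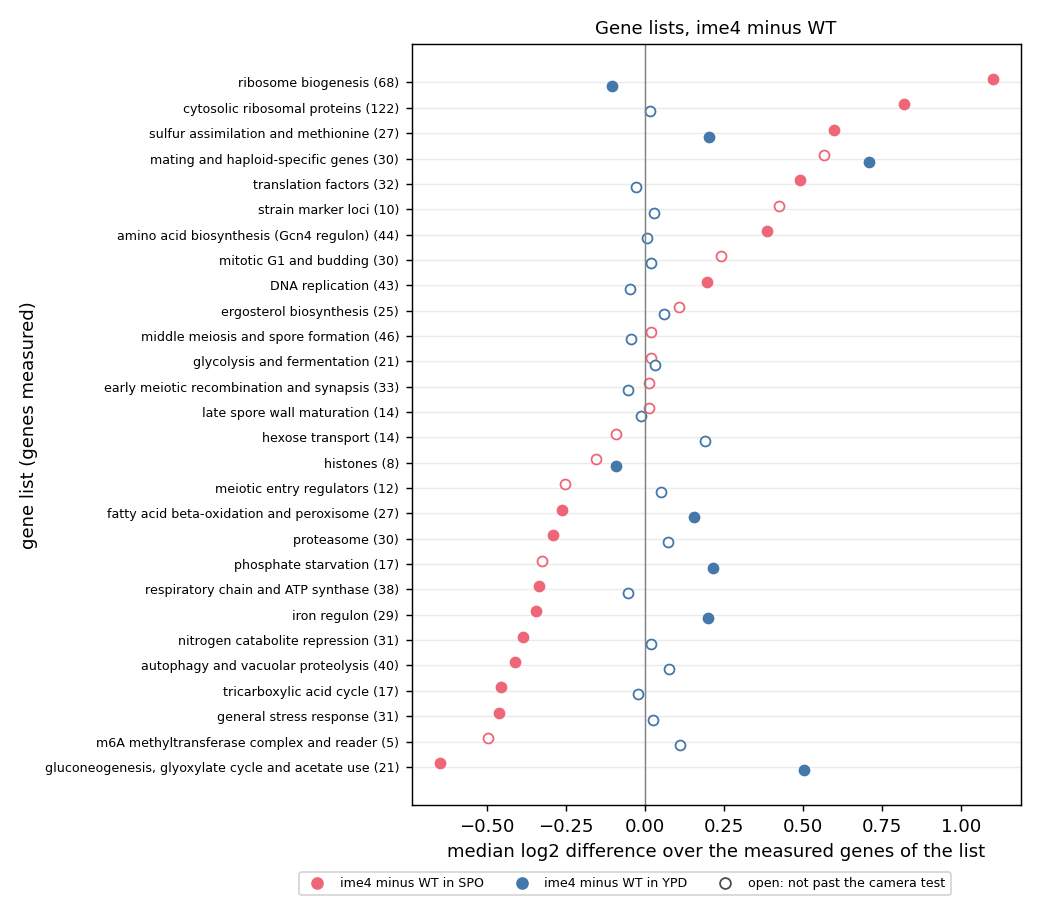
Each row is a gene list with its number of measured genes, and points give the median log2 difference between ime4 and WT in SPO (red) and YPD (blue), filled where the camera test passed at the preset correlation. Ribosome biogenesis (1.10) and ribosomal proteins (0.82) have the highest medians in SPO, and gluconeogenesis and acetate use the lowest (-0.65) although it is the second highest in YPD (0.50).

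In YPD fewer genes passed between the genotypes than in SPO. There, 1141 probe sets were higher and 1003 lower in ime4 (991 and 1110 with centring), and 52 and 49 at least 2-fold. The largest rises outside the mating-type genes were in the phosphate transporter gene PHO89 (6.95-fold), the alcohol dehydrogenase gene ADH2 (6.02-fold) and YAR066W (4.88-fold, shared probes). The alpha-agglutinin gene SAG1 was 18.4-fold and AFB1 43.1-fold higher. The largest falls, beside MFA2, STE2, HMRA1 and IME4, were in AGA2 (44.1-fold) and DSE1 (9.61-fold), each with 1 of 2 ime4 arrays above background, DSE2 (12.3-fold) and the a-cell protease gene BAR1 (7.88-fold). Among the regulators, RME1 was 3.30-fold higher in ime4 (adjusted p = 2.44e-07). IME1 was 1.14-fold higher (adjusted p = 0.0265), which was lost with quantile normalization (adjusted p = 0.27), with centring (0.0622) and without any of the 4 arrays (0.0693 to 0.112). UME6 was 1.18-fold lower (adjusted p = 0.0277, between 0.089 and 0.15 without WT replicate 1 or either ime4 replicate). IME2, RIM4, SLZ1 and PHO92 did not pass. SLZ1 was higher past the threshold with quantile normalization (adjusted p = 0.02), with an intensity trend (0.0492) and without ime4 replicate 2 in YPD (0.00329), and RIM4 without WT replicate 2 in YPD (0.00382).

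Of the genes of gluconeogenesis and acetate use, 15 of 21 were higher and 2 lower in ime4 in YPD (16 and 2 adjusted over the list alone, median 0.50, adjusted p = 1.26e-05, 0.108 with an estimated correlation), PCK1 2.57-fold. On the same arrays the alpha1 transcript was 26.1-fold higher. Ribosome biogenesis genes were lower (24 of 68, with 3 higher, or 5 adjusted over the list alone, adjusted p = 0.00287, 0.112 with an estimated correlation). Ribosomal proteins showed no shift (15 higher, 15 lower of 122, 13 and 11 adjusted over the list alone, adjusted p = 0.974). Sulfur assimilation (14 higher, 2 lower of 27, 15 and 2 adjusted over the list alone, adjusted p = 0.00717), beta-oxidation (12 and 2 of 27, 14 and 2 adjusted over the list alone, adjusted p = 0.0148), phosphate starvation (8 and 2 of 17, the same adjusted over the list alone, adjusted p = 0.0297) and the iron regulon (14 and 3 of 29, 15 and 3 adjusted over the list alone, adjusted p = 0.034) were higher. With an estimated correlation these gave adjusted p = 0.151, 0.122, 0.127 and 0.209, and the phosphate call was lost without the dimmest 25% of probe sets (0.252). The direction of the mating list, which follows, depends on how many a-specific genes (lower in ime4) and alpha-specific genes (higher) it holds. The mating and haploid-specific list was higher (18 and 9 of 30, the same adjusted over the list alone, adjusted p = 0.00949, 0.0847 with an estimated correlation), and histones lower (0 higher, 3 lower of 8, the same adjusted over the list alone, adjusted p = 0.0497, 0.155 with an estimated correlation, and lost without the dimmest 25% at 0.0678, without WT replicate 1 or ime4 replicate 2 in YPD at 0.0885 and 0.065, and without any WT array in SPO at 0.0502 to 0.0525).

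The genes at least 2-fold higher in ime4 in both media numbered 21 (2.97 expected by chance), and those lower in both 16 (0.841 expected). Beside the mating-type genes they included CHA1, DFR1, FLO10 and FRE4 (higher) and URA1, DSE1, DSE2, CTS1 and PHO3 (lower), examples chosen after their values were seen. Across all genes the genotype differences in the media correlated weakly (r = 0.278, rho = 0.062). With 2 or 3 arrays per group and a single time in SPO, the precision rests on a spread pooled over the groups, and the course of the response over time was not measured.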

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

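The interaction contrast, its list tests and the tests of mixed vegetative cells and of probe signal were set before the data were examined, and the other tests of explanations were chosen after the result was seen.

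A test of the difference between the genotypes' responses to SPO called 3433 probe sets. The lists whose responses differed, by their mean interaction in log2, were positive for ribosome biogenesis (1.24), ribosomal proteins (0.778), translation factors (0.484), mitotic G1 and budding (0.448), DNA replication (0.381), sulfur assimilation (0.332) and amino acid biosynthesis (0.243). With an estimated correlation the first 3 of these calls held, and the others gave adjusted p = 0.108, 0.112, 0.122 and 0.139 in this order. The call of mitotic G1 and budding was also lost without the dimmest 25% of probe sets (0.433). They were negative for gluconeogenesis and acetate use (-1.29), the m6A complex (-0.839, IME4 included), phosphate starvation (-0.736), the iron regulon (-0.531), the tricarboxylic acid cycle (-0.506), stress (-0.438), autophagy (-0.437), beta-oxidation (-0.404), the respiratory chain (-0.291), the proteasome (-0.267) and nitrogen catabolite repression (-0.224). None of these negative calls held with an estimated correlation, where the adjusted p was 0.0754, 0.151, 0.0693, 0.0993, 0.137, 0.0588, 0.0588, 0.0754, 0.112, 0.227 and 0.24 in this order.

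Among regulators and meiotic genes the response of ime4 minus that of WT was -1.714 log2 for IME1, -1.177 for IME2, -1.314 for RIM4, -1.424 for RME1, -0.8089 for SLZ1, -0.5843 for RIM11, -0.5622 for RSF1, -0.4563 for RIM101, -0.3038 for MUM2, -1.154 for CSM4 and -0.3553 for SPS100. The MUM2 call was lost with quantile normalization (adjusted p = 0.0881), with centring (0.0641) and without any of 3 arrays (0.0816 to 0.083). The difference was 1.296 for UME6, 1.675 for SUM1 and 0.7663 for CDC5. For groups at background in YPD or in ime4 the size is uncertain, which concerns PHO92 (-1.036), IME4 (-1.796), MFA2 (2.673), CDA2 (2.768) and POX1 (-0.9421). Among metabolic genes it was -1.749 for ADY2, -1.324 for CRC1, -0.5686 for YLR012C, -0.8167 for CTA1, -1.306 for SPG4, -2.266 for FDH1, -0.3076 for POT1, -1.727 for PCK1, -1.296 for CIT3, -3.275 for ADH2, -2.488 for PHO84, -2.463 for URA1, -2.408 for ARO9 and -0.3378 for HXT4. Among genes of growth and ribosomes it was 1.767 for NOP1, 1.065 for NIP7, 1.117 for URA7, 1.256 for NSR1, 1.416 for ELO2, 1.003 for NOP13, 1.591 for INA1, 0.919 for RPL6B, 0.6725 for RPS0B, 0.6851 for AAH1, 2.63 for SPB1, 2.41 for RFU1, 0.531 for RNR1 and 1.458 for POL30. Among mating genes it was 3.415 for STE2, -2.402 for STE3 and -1.598 for MF(ALPHA)2. STE2 was above background on 1 of 2 ime4 arrays and ADY2 on 1 of 2 WT arrays in YPD, so their sizes are uncertain too.

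Signal in probe sets outside the tests, those without a gene name, was at least 2-fold higher in ime4 than in WT for 2 sets in YPD and 7 in SPO. Of the 39 reporter sets, 1 was 1.1 log2 higher in ime4 in YPD and 1.06 in SPO.

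The first pattern weighed was the mating-type difference. The IME4 level gave no sign of an exchange of array labels, since 0 of 9 arrays had IME4 on the side of the other genotype. It cannot exclude an exchange, because IME4 and the mating-type transcripts differed together on every array. Whether the IME4 level follows the mating type was not tested. The order of a1 and alpha1, also out of place on 0 arrays, is the pattern itself and adds no test. A mix-up of strains or cultures was not tested. Cultures of a/alpha cells in both genotypes did not account for the difference either, since the a1 level of the ime4 arrays in YPD lay at -1.41 log2 from background. WT cultures that held a/alpha cells beside a cells remain a possible explanation of the WT pattern, since haploid-specific genes were 1.31 log2 lower in WT (median). This set was written after its values had been seen. Loss of IME4 itself cannot be told apart from a difference of strains, because 0 arrays carried 1 genotype with the mating-type pattern of the other.

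The second pattern was the smaller response of ime4 to SPO. A compression of the ime4 arrays in SPO by the same factor at all intensities would shrink all lists alike. The ratio of the responses was instead 0.37 higher for beta-oxidation than for ribosome biogenesis (95% interval 0.305 to 0.443), lists picked after their values were seen. A compression that depends on intensity could shrink lists unequally and was not tested. Vegetative cells as the only difference, with intensities linear in RNA, would give the same share from rising and falling genes. The shares were 34% over 196 genes 8-fold higher and 10.8% over 111 genes 8-fold lower, a difference of 0.232 (0.19 to 0.269). They were solved with WT in SPO and ime4 in YPD as the unmixed states. A contribution of vegetative cells beside another difference was not tested. The intervals rest on resampled genes, which are not independent replicates. Loss of IME4 and mating type cannot be told apart as sources of the slope of 0.792, and a delay of the ime4 response was not tested.

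The third pattern was that neither NDT80 (0.28 log2) nor, with camera, the middle list passed the threshold for a rise in WT. NDT80 read 3.35 to 4.372 log2 over the 9 arrays, near the background levels of 3.02 to 3.27, so a small rise could be missed. The middle list did pass with fry (adjusted p = 4.13e-05), which does not compare it with other genes. In WT 12 of its genes rose at least 2-fold. Cells that are not a/alpha are a possible explanation, since a-specific genes, which a/alpha cells repress, had a median 4.24 log2 above background in WT in SPO. This set, too, was written after its values had been seen. Probe sets without signal cannot be told apart as a source, since 60.9% of the middle sets lay at least 1 log2 above background. A time before the middle genes rise cannot be told apart either, because 1 time was sampled.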

How the results depend on the processing

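The alternatives were chosen before the data were examined, and none was added later. With quantile normalization, centring, the dimmest 25% of probe sets left out, an intensity trend with robust variances, array weights, the replicate number as a block, or the arrays of the compared groups only (not applicable to the interaction), the count of changed genes stayed within 1.5 times its value in each of the 5 contrasts. With a 2-fold threshold in addition the counts fell, by construction, from 3936 to 398 (ime4 against WT in SPO), 2144 to 101 (in YPD), 4821 to 2316 (SPO against YPD in WT), 4609 to 1790 (in ime4) and 3433 to 535 (interaction). Centring shifted the median of all genes by -0.103 log2 for SPO against YPD in WT and by less than this elsewhere. The balance of higher and lower genes depended on the scale. The share of higher genes among those changed, as reported, with quantile normalization and with centring, was 46.4%, 44.5% and 50.7% (genotypes in SPO), 53.2%, 49% and 47.2% (in YPD), 52.1%, 49.3% and 48.3% (SPO against YPD in WT), 51.1%, 47% and 48.9% (in ime4), and 46%, 45.6% and 52.7% (interaction).

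Leaving out 1 array at a time gave 3552 to 3963 changed genes for the genotypes in SPO, 1580 to 2115 in YPD, 4668 to 4828 for the response of WT, 4402 to 4631 for that of ime4 and 3148 to 3338 for the interaction. A group left with 1 array was assumed to vary like the others. The slope of the ime4 on the WT response was 0.7883 (without WT replicate 1 in YPD) to 0.7941, and 0.7953 with the dimmest 25% left out, against 0.792; the cause was not tested. The number of lists past the threshold was 15 to 16, 7 to 9, 18 to 19, 19 to 20 and 18 to 18 in the same order of contrasts.

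With an estimated correlation, camera passed 4 lists in place of 15 for the genotypes in SPO, 0 in place of 8 in YPD, 6 in place of 19 in WT, 6 in place of 19 in ime4 and 3 in place of 18 for the interaction. That alternative replaces the preset 0.01 by values estimated from 5 residual degrees of freedom. Fry, which does not compare a list with other genes, passed 24 (SPO) and 18 (YPD). With the replicate number as a block the counts were 3740, 1941, 4752, 4587 and 3250, the lists 16, 8, 19, 19 and 18, and the slope 0.7924. The residuals of arrays with the same number correlated with r from -0.0204 to 0.0314, so no shared effect of the replicate number was seen. Some of these values repeat between replicate numbers and are not separate checks. Whether arrays with the same number came from paired cultures cannot be decided from them, since a pairing need not leave a shared effect.

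Among the named genes, quantile normalization reversed the direction of HTA2 (shared probes) for SPO against YPD in ime4, from -0.22 log2 to 0.1265. It weakened 5 other gene results past the threshold and strengthened 4; centring weakened 3. With the dimmest 25% left out, 12 list results lost their call, 1 gained one and 1, the early recombination list in the response of ime4, changed direction (adjusted p = 0.94); fewer genes of the meiotic lists were tested there, and the cause was not tested beyond this. Without 1 array, 36 gene results were lost and 16 gained, and 3445 stayed on their side of the threshold, called or not. Signal over background limits several meiotic lists: 11 of 33 early, 13 of 46 middle, 5 of 14 spore wall and 2 of 5 m6A genes were at background in at least 1 group.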

Other observations

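The test of whole chromosomes was set before the data were examined, and the other values here were picked after they were seen.

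Further genes separated the genotypes in both media. URA1, which encodes dihydroorotate dehydrogenase, was 1.64 log2 lower in ime4 in YPD (adjusted p = 3.92e-08) and 4.11 lower in SPO. Its WT levels were alike in the media (11.04 and 11.16), and its ime4 level was lower in SPO (7.06) than in YPD (9.40). The genes of daughter-cell separation DSE1, DSE2 and CTS1 were lower in ime4 in both media (CTS1 -2.44 in YPD and -1.73 in SPO). The flocculin gene FLO10 was higher in both, by 1.05 and 2.11.

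The hypothesis that the ime4 strain gained or lost a whole chromosome was tested by the median genotype difference of each chromosome in YPD. The median farthest from 0 was 0.154 log2, for the 146 genes of chromosome III, which carries the mating-type locus. It was also 0.154 over the 144 genes of this chromosome that are not among the mating-type markers examined. In SPO the median of the 146 genes was 0.179. A gain from 2 to 3 copies in every cell would give 0.585 if signal followed copy number, and a shift of this size was not seen. The ploidy was not given, and another starting copy number would give another value. In YPD, 71.9% of the genes of chromosome III were higher in ime4, against 53.6% on the other chromosomes, and in SPO 65.1% against 46.3%. A gain in some of the ime4 cells, or a loss in some of the WT cells, was not tested.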
